A study of Mus musculus with 2 samples.

How the data were processed

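Gene expression was measured on Affymetrix arrays in differentiated C2C12 cells, a mouse myoblast line that fuses into myotubes in low-serum medium. Per the labels' protocols, cells were grown in medium with 10% fetal bovine serum, switched at confluence to 2% horse serum for 7 days, and infected for 48 h at a multiplicity of infection of 30 with 1 of 2 adenoviral vectors. Ad-caERα carries a constitutively active estrogen receptor α, and Ad-DsRed carries the red fluorescent protein DsRed and served as the control vector. Biotin-labelled cRNA was made from 150 ng of total RNA. Group names came from the sample titles; 1 further label of the Ad-caERα sample spells the receptor's Greek letter differently from its title.

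The deposited values are log2 signals per probe set, 1 column per sample. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, a method that corrects background, quantile-normalizes arrays and summarizes the probes of each probe set. Versions, the number of arrays normalized together and any probe filter are not given in the sources used here. RMA compresses differences between weak signals, and quantile normalization hides any change in total mRNA between the cultures. The table held 35556 probe sets. The column medians were 6.05 for Ad-DsRed and 6.02 for Ad-caERα, with no centring of genes, and values ran from 1.85 to 14.16 and from 1.89 to 14.13. Detection calls, probe-level signals and scanner dates were not analysed here, so the precision of each value is unknown.

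Genes were named from the platform's annotation table, which named 1 gene for 21789 probe sets and several genes for 1621; the other 12146 are unnamed here. Gene identifiers of 21698 single-gene probe sets matched the RefSeq table of assembly GRCm38.p6, which changed 0 symbols. Probe sets with several genes were given no name. For 999 of the 19938 named genes with over 1 probe set, the probe set with the highest mean of the 2 arrays was used.

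A detection floor was set from genes that a muscle line is not thought to express. It was the 95th percentile of the higher of the 2 values over 1212 probe sets of olfactory and vomeronasal receptor genes, a log2 signal of 5.11. Genes whose higher value passed the floor were called measured, 13556 in all, with the receptor genes left out. The difference is the Ad-caERα value minus the Ad-DsRed value on the log2 scale. Where the dimmer array lay below the floor, the fold is given as at least the brighter signal over the floor. Counts with all values below the floor raised to it, chosen after seeing the data, are given beside those on the values as deposited.

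With 1 array per group no test between the groups could be made, and no p-value or standard error is given. Genes were counted by a rule of size, a difference of at least 2-fold. The named genes follow a rule fixed before the data were examined: Esr1, the 12 measured genes with the largest difference in each direction (leaving out unnamed gene models, small RNAs and the receptor genes), members of the estrogen receptor target and nuclear receptor lists past the 2-fold rule, and, in each list described, up to 2 members with the highest and 2 with the lowest difference. Other cell types' markers past the 2-fold rule were named too. A few further members are named for what they encode and were chosen after their values were seen.

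The 32 gene lists were fixed at the same stage. Each list's median difference over its measured members was set among 10000 random lists of the same size, matched on mean level in 20 equal bins. The percentile describes these 2 arrays and is no test of the vectors. Lists share members, and genes of a list vary together. The code was tested on simulated data with 13556 genes and independent normal noise of SD 0.21, taken from the middle of these same differences. The 2-fold rule recovered 98.0% of genes changed by 1.5 and 100% of those changed by 2 on the log2 scale, and called 0 unchanged genes. Of 40 simulated lists of 30 genes, 3 lay outside the central 95% without a shift, and 40 lay above it with a shift of 0.2. The spread between cultures is unknown and real list members vary together, so these figures check the code and give no error rate for these arrays. Alternatives covered the floor, the normalization, the rule for several probe sets, the fold threshold, the list summary and the matching. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.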

Results

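Total RNA from differentiated C2C12 myotubes that received a constitutively active estrogen receptor α (Ad-caERα) or the DsRed control vector (Ad-DsRed) was profiled on 2 arrays, 1 per vector. The comparison asks which transcripts differ between myotubes expressing the active receptor and those expressing the control protein. The design has 1 array per group, so the differences below have no replicate check. Of the 35556 probe sets, 63.2% passed the detection floor in Ad-DsRed and 62.2% in Ad-caERα. The arrays correlated at r = 0.990 across the 13556 measured genes, which are not independent replicates. As yardsticks of measurement spread, the difference had an SD of 0.22 on the log2 scale over 1212 receptor probe sets taken as silent. It had an SD of 0.11 over 53 ribosomal protein genes and of 0.13 between probe sets of the same gene, from 770 genes.

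Esr1 and 3 of 31 measured estrogen receptor target genes passed the 2-fold rule upwards in the array with the active receptor. Esr1, which encodes estrogen receptor α, had a log2 signal of 8.44 in Ad-caERα against 7.38 in Ad-DsRed, a 2.08-fold difference. The labels do not say which part of the receptor, or from which species, the vector carries, so the probe set reads the endogenous and the introduced transcript to an unknown extent. Greb1, an estrogen receptor cofactor and target, was at least 18.5-fold higher, with a log2 signal of 9.31 against one below the floor. Pgr, the progesterone receptor, was at least 4.17-fold higher, and Ccn5, a matricellular protein gene, was 2.59-fold higher at 8.74 against 7.37.

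These 3 were the only members of the list past the rule, and 0 were lower by it. The list's median difference was 0.064, at the 91.7th percentile of matched random lists, and 0.12 with either higher floor (97.2nd and 96.4th percentiles). Its mean was 0.29, above all 10000 random lists, but it rests largely on Greb1, Pgr and Ccn5 and shows no shift of the whole list. The lowest members were Mybl1 (a difference of -0.37) and Trim25 (-0.36), an estrogen-responsive ubiquitin ligase gene. Tff1 (-0.092), Ctsd (0.12) and Myc (0.12), all induced by estrogen in breast cancer cells, differed by less than the SD of 0.22 over the silent receptor probe sets. Most of those probe sets lie below the floor, whereas Ctsd and Myc are bright. Against the SD of 0.11 over ribosomal protein genes, the differences of Ctsd and Myc were not smaller. Among 25 measured nuclear receptors and coactivators the median was -0.023 (23.8th percentile), while the mean was 0.16 (99.1st percentile) and the median 0.039 with either higher floor. Only Pgr and Esr1 passed the 2-fold rule there, and the lowest were the coactivators Ppargc1b (-0.53) and Ppargc1a (-0.43), which drive mitochondrial gene expression. Esr2, which encodes estrogen receptor β, was below the floor on both arrays.

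**Figure D1:**
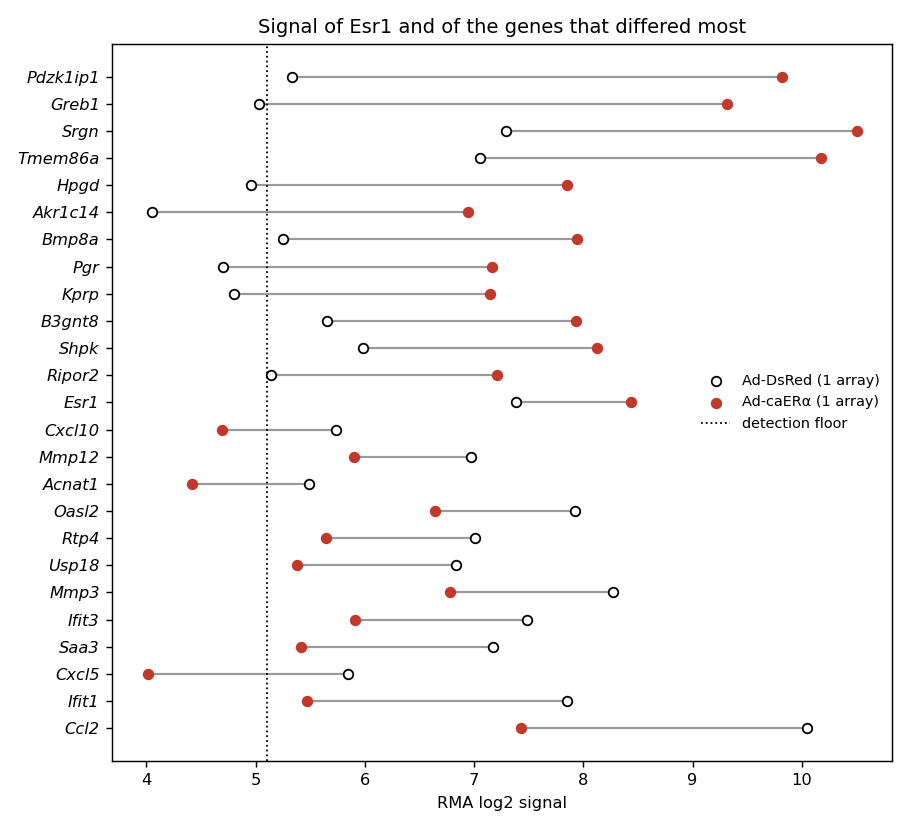
Log2 signal (x axis, RMA) of Esr1 and of the 12 genes with the largest difference in each direction (y axis). Open circles are the Ad-DsRed array, filled circles the Ad-caERα array, 1 array each, and the dotted line is the detection floor of 5.11; Greb1 runs from below the floor to 9.31, and Ccl2 from 10.04 down to 7.43.

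Past the 2-fold rule, higher genes outnumbered lower ones, whereas 50.2% of all measured genes lay above 0. On the values as deposited 80 genes were higher and 13 were lower by that rule, which is 0.686% of the measured genes. Among the silent receptor probe sets 2 of 1212 were that far apart. Most of these lie below the floor they set, where differences are compressed, so this share is no background rate for measured genes. Of 7017 unnamed probe sets above the floor, of unknown kind, 3.28% passed the rule. With values below the floor raised to it, 74 genes were higher and 9 lower. At 4-fold these counts were 11 higher and 2 lower. The largest difference on the values as deposited was in Pdzk1ip1, which encodes a small membrane-associated protein, at 9.82 against 5.34 (22.3-fold). For Greb1, next in rank, the fold is only a lower bound. Srgn, the secretory granule proteoglycan serglycin, was 9.25-fold higher and Tmem86a 8.71-fold higher. Metabolic enzymes among the 12 highest genes were Hpgd, which inactivates prostaglandins (at least 6.71-fold), Akr1c14, an aldo-keto reductase that acts on steroids (at least 3.57-fold), B3gnt8, a glycosyltransferase (4.86-fold), and Shpk, which phosphorylates sedoheptulose (4.42-fold). Bmp8a, a ligand of the TGF-β superfamily, was 6.47-fold higher, Ripor2 4.18-fold higher, and Kprp at least 4.12-fold higher.

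**Figure D2:**
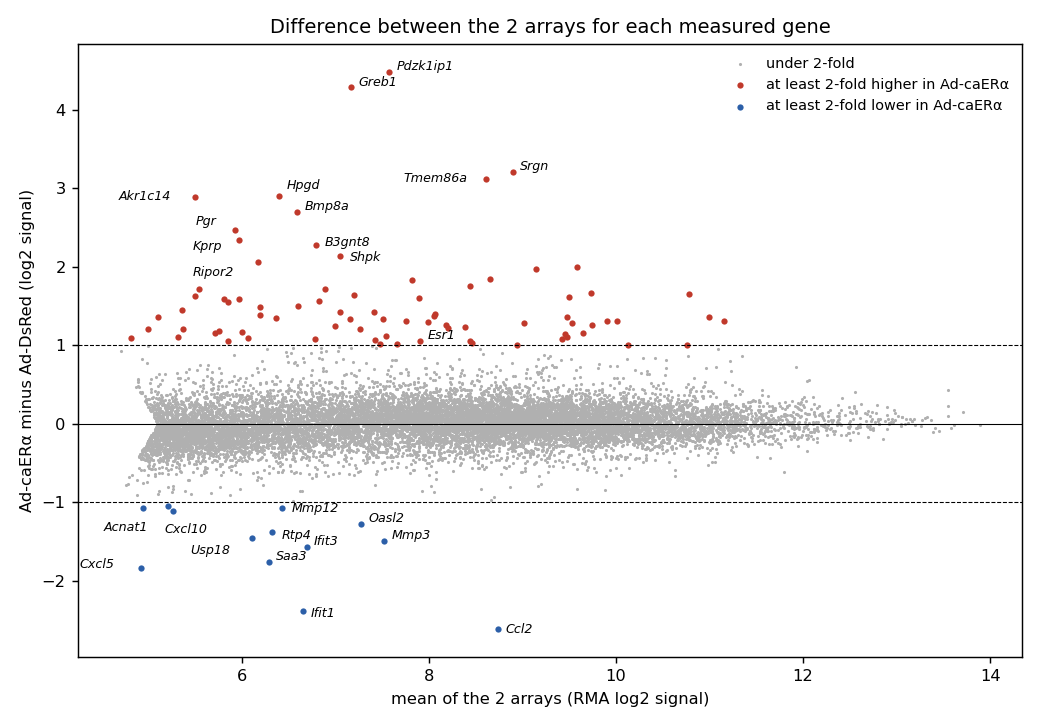
Difference between the arrays (y axis, Ad-caERα minus Ad-DsRed, log2) against the mean of both arrays (x axis, RMA log2 signal) for 13556 measured genes, 1 point per gene. Dashed lines mark the 2-fold rule, passed upwards by 80 genes and downwards by 13, with Esr1 and the 24 most different genes labelled.

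The interferon-stimulated and inflammatory gene lists were lower in the array with the active receptor. Of 28 measured interferon-stimulated genes, 24 were below 0. By the 2-fold rule 5 were lower and 0 higher on the values as deposited, and 4 were lower with values below the floor raised to it. The list's median difference was -0.46, below all 10000 random lists. Ifit1, an inhibitor of viral RNA translation, was 5.22-fold lower at 5.47 against 7.85, and Ifit3 was 2.97-fold lower. Usp18, which removes the ubiquitin-like protein ISG15, was 2.74-fold lower and Oasl2 2.42-fold lower. The chemokine gene Cxcl10 was below the floor in Ad-caERα and at least 1.54-fold lower. The highest members were Tap1 (0.39), a peptide transporter of antigen presentation, and Ifi27 (0.16). Rtp4, an interferon-induced gene outside the list, was 2.59-fold lower. Other interferon-inducible genes outside the list, chosen after their values were seen, went both ways: Tap2 was 2.32-fold higher, Gbp8 at least 2.46-fold and Gbp4 at least 1.41-fold, while Gbp2b had a difference of -0.57. Some probe sets are shared by several Gbp genes, so these signals cannot be assigned to single members with certainty.

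In the inflammatory and NF-κB list, 16 of 22 measured members were below 0. By the 2-fold rule 4 were lower and 0 higher on the values as deposited, and 3 were lower with values below the floor raised to it. The median was -0.28, below all random lists. Ccl2, the monocyte chemoattractant, had the lowest difference of the measured genes, at 7.43 against 10.04 (6.11-fold lower). Saa3, an acute phase protein gene, was 3.38-fold lower and the matrix metalloproteinase gene Mmp3 2.80-fold lower. Cxcl5, a neutrophil chemokine, was below the floor in Ad-caERα and at least 1.67-fold lower. Of the 6 members above 0, the highest were Nfkbia (0.84), which encodes the NF-κB inhibitor IκBα, and Cebpb (0.70). Outside both lists, Mmp12 was 2.10-fold lower and Acnat1 at least 1.30-fold lower.

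Cell cycle transcripts were lower as a group by a small amount. All 38 measured members of the cell cycle and replication list were below 0, although 0 of them reached 2-fold. The median difference was -0.23, below all 10000 random lists. The lowest were Cenpe, a centromere motor (-0.56), and Ect2, a regulator of cytokinesis (-0.56), and the highest were Fen1 (-0.012) and Mcm10 (-0.016). Mki67, the Ki-67 proliferation antigen, had a difference of -0.44 and Top2a of -0.44. Of the 24 fixed p53 target genes 20 were measured, and Cdkn1a, Bax, Gdf15 and Perp were not. The p53 target list had a median of -0.12 (0.360th percentile), with 17 of the 20 measured members below 0. Its lowest members were the pro-apoptotic gene Pmaip1 (-0.67) and Plk2 (-0.45), and its highest Zmat3 (0.47) and Phlda3 (0.27).

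The sarcomere, fast fibre, slow fibre and excitation-contraction coupling lists had medians slightly below 0. No member of these lists passed the 2-fold rule. The sarcomere list had a median of -0.084 over 43 genes (0.0300th percentile), with Lmod3, a thin-filament nucleator (-0.82), and Actc1, cardiac α-actin (-0.62), at the bottom and Mybpc2 (0.65) and Myh7 (0.50) at the top. Excitation-contraction coupling genes had a median of -0.14 over 28 genes (0.0200th percentile), the lowest being Casq1, a calcium-binding protein of the sarcoplasmic reticulum (-0.61), and Atp2a1, its calcium pump (-0.52), and the highest Pln (0.34) and Ryr3 (0.33). Fast fibre genes had a median of -0.11 over 13 genes (1.92nd percentile; 2.66th without a floor, within the central 95%), running from Casq1 and Atp2a1 up to Myl1 (0.0099) and Mybpc2. Slow fibre genes had a median of -0.076 over 12 genes (5.33rd percentile) but a mean of 0.025, with myoglobin, Mb (0.87), and Myh7 highest and Casq2 (-0.45) and Myoz2 (-0.39) lowest.

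Myogenic regulators and fusion genes had a median of -0.13 over 20 genes (0.120th percentile), with 12 below 0. The mean over the same genes was -0.024 (15.6th percentile). Myf6 (0.87) and Myf5 (0.71), both myogenic transcription factors, were highest, and the fusion gene Mymx (-0.79) and Six4 (-0.51) were lowest. Myod1 was at 10.84 in Ad-DsRed and 10.85 in Ad-caERα. Undifferentiated myoblast markers had a median of -0.14 over 20 genes (0.0600th percentile), with Vcam1 (-0.94) and Met (-0.57) lowest and Myf5 and Id2 (0.42) highest. The markers split in direction, 11 below 0 and 9 above, so the low median is no fall of the whole group. Their mean was -0.093 (0.750th percentile). Vcam1 is also in the inflammatory list and Mki67 in the cell cycle list. Muscle atrophy and autophagy genes had a median of 0.028 over 31 genes (54.4th percentile), from Bnip3 (0.63) and Map1lc3a (0.53) to Klf15 (-0.19) and the ubiquitin ligase gene Trim63 (-0.13).

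Oxidative phosphorylation, glycolysis and antioxidant genes were slightly higher as groups. In the oxidative phosphorylation list 69 of 74 members were above 0, with a median of 0.15, above all 10000 random lists, and 0 reached 2-fold. Atp5e (0.51) and Ndufa7 (0.49), subunits of ATP synthase and complex I, were highest, and the muscle isoforms Cox8b (-0.23) and Cox6a2 (-0.046) of cytochrome c oxidase were lowest. Glycolysis and glycogen genes had a median of 0.16 over 24 genes (99.96th percentile), with 21 above 0. Pgm1 (0.74) and Pfkl (0.45) were highest and Slc16a1 (-0.043) and Pgam2 (-0.035) lowest. Antioxidant and glutathione genes had a median of 0.12 over 32 genes (99.4th percentile). Gpx3, a secreted glutathione peroxidase, was 3.16-fold higher, Sod3 followed at 0.52, and Gsta4 (-0.46) and Txnrd1 (-0.19) were lowest. The ribosomal protein list, included as a control, had a median of 0.071 (96.2nd percentile), with 43 of 53 above 0, from Rpl14 (0.47) and Rpl34 (0.41) to Rps20 (-0.12) and Rpl12 (-0.11).

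Fatty acid uptake and oxidation genes had a median of 0.062 over 29 genes (87.3rd percentile). It was 0.12 with either higher floor (97.9th and 98.0th percentiles), and the mean was 0.13 (99.3rd percentile). Lpl, lipoprotein lipase, was 3.94-fold higher, Acot1 was at least 1.26-fold higher, and the lowest members were Angptl4, an inhibitor of lipoprotein lipase (-0.44), and Ucp3, a mitochondrial uncoupling protein (at least 1.08-fold lower). Cholesterol and fatty acid synthesis genes had a median of 0.021 over 24 genes (42.8th percentile). The TCA cycle list was at 0.031 over 27 genes (57.6th percentile), with the pyruvate dehydrogenase kinase Pdk1 (0.69) and Pcx (0.45) highest and Dld (-0.12) and Idh2 (-0.084) lowest. Glutamine and amino acid metabolism was at 0.087 over 24 genes (91.0th percentile), with Got1 (0.67) and Bckdha (0.65) highest and Slc38a1 (-0.39) and Phgdh (-0.39) lowest, and mitochondrial biogenesis and dynamics at 0.011 over 30 genes (36.9th percentile).

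Among the remaining lists, extracellular matrix genes had a median of -0.012 over 41 genes (20.1st percentile), yet Thbs2, a matricellular thrombospondin, was 2.58-fold higher, Col12a1 was at 0.83, and Col18a1 (-0.45) and Adamts5 (-0.36) were lowest. Circadian clock genes were at 0.076 over 17 genes (79.8th percentile), with Ciart (0.82) and Nfil3 (0.81) highest and Nr1d2 (-0.25) and Hlf (-0.17) lowest. Heat shock proteins were at 0.013 (46.1st percentile), unfolded protein and integrated stress response genes at 0.096 (95.4th percentile), and signalling feedback and growth factor genes at -0.062 (3.10th percentile), with Igf1 (0.47) and Ier3 (0.24) highest and Ier2 (-0.52) and Egr1 (-0.46) lowest. The last list lay below the central 95% of its random lists under 5 of the other settings, and the mean of the circadian list was 0.20 (98.4th percentile). The stress response list lay above the central 95% when probe sets were averaged.

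Leukocyte, endothelial and osteoblast markers were mostly below the floor. Of 15 leukocyte markers on the array 3 were measured (median 0.25, 96.1st percentile), while the median over all 15 without a floor was -0.033, and Ptprc, Csf1r, Adgre1 and Lyz2 were below the floor on both arrays. Of 12 endothelial markers 5 were measured (median -0.12, 33.0th percentile), and of 6 osteoblast markers 1, Alpl (-0.061). Of 12 adipocyte markers 7 were measured (median -0.061, 45.1st percentile; mean 0.17, above the central 95%). Among these only Lpl, which muscle also expresses, passed the 2-fold rule, while Adipoq and Fabp4 were below the floor. Smooth muscle and fibroblast markers had a median of 0.040 over 12 genes (76.9th percentile), from Tagln (0.59) to Pdgfrb (-0.39). In all, 12 of the 32 lists lay outside the central 95% of their random lists, 9 below and 3 above. If lists were independent draws, 1.6 would do so. The lists share members and genes of a list vary together, so 1.6 is no chance rate for them. The 12 are not separate results: all measured fast fibre genes are also in the sarcomere or excitation-contraction coupling list.

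**Figure D3:**
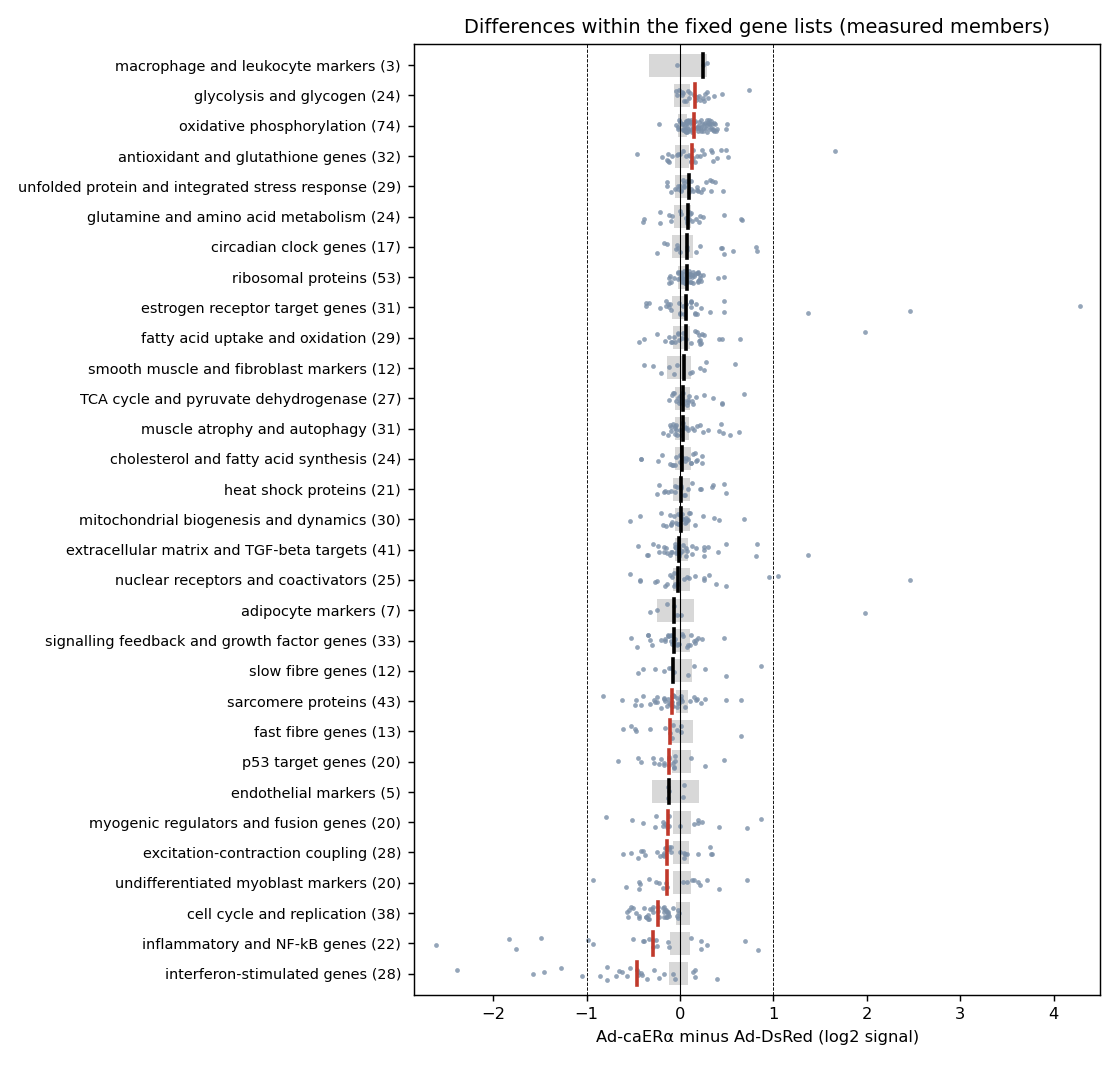
Difference of each measured member (points; x axis, Ad-caERα minus Ad-DsRed, log2) in the fixed lists with at least 3 measured members (y axis, number in brackets). Vertical bars are list medians, red where outside the central 95% of 10000 matched random lists (grey), and dashed lines mark 2-fold; interferon-stimulated genes lie lowest at -0.46, and glycolysis (0.16) and oxidative phosphorylation (0.15) are the highest of the red medians.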

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

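No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out; array-to-array and culture-to-culture spread are therefore unknown, and signals below the floor give only bounds on a fold. The counts of 80 higher and 13 lower genes stayed between 74 and 81 and between 9 and 13 under the other floors, centring, loess correction, quantile normalization and averaging of probe sets. They moved with the threshold itself, to 247 and 120 at 1.5-fold and to 27 and 4 at 3-fold. Centring, quantile normalization and averaging of probe sets could hardly change the counts. Per the submitters' notes RMA had been applied already, the median difference was 0.0017, and 999 of 19938 named genes had over 1 probe set. Raising values below the floor to it, an alternative chosen after seeing the data, gave 74 and 9 genes; Cxcl5, Acnat1 and Cxcl10 then lost their 2-fold difference, at -0.74, -0.38 and -0.63, and the interferon and inflammatory medians were -0.43 and -0.25. All 12 lists outside the central 95% stayed on their side of 0 in 108 recalculations, of which 105 moved by less than the SD of the random-list medians. The 3 others came from taking means over members: -0.56 for interferon-stimulated genes, -0.46 for inflammatory genes and -0.024 for myogenic regulators, the last within its random lists. Some recalculations could hardly move a list. Centring shifts all genes by the same small amount, and the oxidative phosphorylation and cell cycle medians were identical under every floor. The number of lists outside ranged from 11 to 18. Fast fibre genes dropped out without a floor or without matching. Ribosomal proteins and signalling feedback genes joined under 5 settings each, among them 100 bins of level, a setting chosen after seeing the list medians. Fatty acid oxidation and adipocyte markers joined with either higher floor, where 2 adipocyte markers were left (median 0.96), and as means. The higher floors were the 99th percentile over receptor probe sets and the median over all probe sets. They nearly coincide, with 10897 and 10886 measured genes and the same list medians, so they are not separate checks. Estrogen receptor targets and nuclear receptors joined as means. These means rest largely on Greb1 (4.28), Pgr (2.47) and Ccn5 (1.38) in the first list, and on Pgr and Esr1 (1.05) in the second. Circadian genes joined as means too, and stress response genes when probe sets were averaged. The cause of the other changes was not tested. Of the lists within their random lists, 10 changed sign under at least 1 setting: cholesterol synthesis, heat shock, mitochondrial biogenesis, muscle atrophy, nuclear receptors and the single osteoblast marker under loess correction or quantile normalization; leukocyte markers without a floor; nuclear receptors and adipocyte markers with a higher floor; and these last 2, cholesterol synthesis, slow fibre and extracellular matrix genes as means.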

Other observations

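The genes and families in the first 2 paragraphs were chosen after their values were seen. The following are single genes among the 80 past the 2-fold rule upwards that the report does not describe, and no shared function was tested. Tgfb2, a transforming growth factor, was 3.99-fold higher in Ad-caERα at 10.59 against 8.59, and Gas6, a ligand of TAM receptor kinases, was 2.62-fold higher. Nppc, which encodes C-type natriuretic peptide, was 2.54-fold higher, and Has2, which makes hyaluronan, was 2.43-fold higher. Apobec2 was 3.13-fold higher at 11.61 against 9.96, Camk2b, a calcium/calmodulin-dependent kinase subunit, 3.58-fold higher, and Tmod1, a thin-filament capping protein, 2.01-fold higher. These 3 are in none of the fixed lists; the sarcomere and excitation-contraction coupling lists went the other way, with medians of -0.084 and -0.14. Padi2, a peptidylarginine deiminase, was 3.55-fold higher. Socs2, a cytokine signalling suppressor, was 2.01-fold higher.

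The guanylate-binding proteins, an interferon-inducible GTPase family, split in direction. Gbp3 was at least 1.64-fold lower, and Gbp7 and Gbp2b were lower with differences of -0.62 and -0.57, whereas Gbp8 was at least 2.46-fold higher, Gbp4 at least 1.41-fold, Gbp9 at least 1.18-fold and Gbp11 at least 1.05-fold. A probe set shared by 6 members of the family (Gbp4, Gbp6, Gbp8, Gbp9, Gbp10 and Gbp11) was at 6.70 against 4.52, and one shared by Gbp2 and Gbp2b was lower, at 6.35 against 6.89. With probe sets shared in this way, the signals cannot be assigned to single members with certainty. Tap2 was 2.32-fold higher. Of 50 measured small nucleolar and Cajal body RNAs, 39 were above 0, with a median of 0.43, and 5 passed the 2-fold rule upwards (4 with values below the floor raised to it), such as Snora52 at 11.81 against 10.50. All 77 probe sets of Hmcn1, an extracellular matrix gene, were below 0, with a median of -0.64 ± 0.18 (SD over probe sets of the same 2 arrays, not replicates). Probe sets that the annotation leaves unnamed differed more than named genes: 3.28% of the 7017 above the floor passed the 2-fold rule on the values as deposited, 123 higher and 107 lower. With values below the floor raised to it, 1.60% did, 59 higher and 53 lower, against 0.612% of the named genes. Whether these probe sets read transcripts or are array controls was not examined, so this is no result about unnamed transcripts. The highest difference was in probe set 10386115, at 8.04 against 4.38, and the lowest in 10340089, at 2.15 against 5.28, which is under 2-fold once raised to the floor.

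In the weighing that follows, the tests of vector load, of the myoblast share and of short transcripts, and the matching in 100 bins, were chosen after the list medians were seen; in each case the effect of the receptor itself was not tested, because vector and array coincide. The first pattern is the lower level of interferon-stimulated and inflammatory genes. A trend of the difference with signal level does not account for it: after loess correction the interferon list's median was -0.49, against -0.46 before, still below all random lists. A different load of vector, or of a contaminant that triggers innate sensing, in the 2 cultures may give the same picture. If the load was lower in Ad-caERα, which was not measured, most members would lie below 0, as 24 of 28 did. An effect of the active receptor that lowers these genes predicts the same. With 1 culture per vector these cannot be told apart, and the count could not have separated them. Of genes outside the list picked after their values were seen, Tap2, Gbp8, Gbp4, Gbp9 and Gbp11 went the other way. For Gbp9 and Gbp11 the bounds were only 1.18-fold and 1.05-fold. Gbp2b was lower, as was Rtp4 (2.59-fold), which is outside the list and was named by the fixed rule.

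The second pattern is the cell cycle list, with all 38 members below 0. A trend with signal level is argued against by a median of -0.25 after loess correction, against -0.23 before, but a bias by transcript length was not tested and stays open. A lower share of undifferentiated, dividing myoblasts in the Ad-caERα culture may contribute. It would lower the other myoblast markers too. Their list, Mki67 included, had a median of -0.14 (0.0600th percentile), but only 10 of 19 others were below 0. Many are also expressed in myotubes, so this count does not decide the question. The sarcomere median was tried first, since a higher myotube share would raise it. It was -0.084 (0.0300th percentile, 31 of 43 members below 0), the opposite direction, which by itself goes against a higher myotube share. It was replaced by the count of 10 of 19 myoblast markers because a high baseline could hide a small rise. A high baseline does not account for a fall.

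The third pattern is the slightly higher level of oxidative phosphorylation and glycolysis genes. It does not follow from signal level: the oxidative phosphorylation median was 0.14 after loess correction, above all random lists matched in 100 bins. If the Ad-caERα array had recovered short transcripts better, ribosomal protein genes, which are short too, would be expected to shift as far. Their median was 0.071 against 0.15, a gap of more than 2 SDs of the random-list medians, but small nucleolar and Cajal body RNAs were mostly higher (median 0.43) and the probe sets of Hmcn1, a long transcript, were lower (median -0.64), as such a bias would give. This explanation therefore stays open, since transcript lengths were not analysed here.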
